A study of Mus musculus with 29 samples.

How the data were processed

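RNA was measured in 29 mouse samples, one Clariom D array (MTA 1.0) per sample, each from 150 ng of total RNA per the labels. The samples were embryonic stem cells and cells at 3 later stages of neural differentiation, from a wild-type line and from a line labelled BERKO, the name for a knockout of estrogen receptor beta (ERβ, gene Esr2). Part of the cells received the ERβ agonist LY3201 at 0.5 nM. Per the labels, the authors made the deposited values with SST-RMA in Affymetrix Expression Console 1.4, which applies a signal space transformation, background correction, normalization between arrays and a summary per transcript cluster. The deposited values are on a log2 scale, 1 value per transcript cluster and array, and were used as given. RMA and the Transcriptome Analysis Console are also named in the submitters' notes, without versions. The genome build behind the array's clusters was not stated, so no coordinates are given.

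The table held 72688 entries, of which 65956 were transcript clusters and 6732 were controls and spike-ins, 5222 of them negative controls. A table of cluster annotation paired 30604 clusters with 1 gene symbol and 2146 with several, and 33206 clusters had no symbol. For 827 clusters the symbol was updated through the gene ID. Clusters with 1 symbol covered 30142 genes. For 355 genes with more than 1 cluster, the cluster with the highest mean over all arrays was used. Another cluster of the same gene gave another value for some named genes: between genotypes, Fas differed by 1.11 with the cluster used and by -0.07 with the other in mDPC, and Mep1b by -1.29 and -1.78 in mESC. A gene was tested when it exceeded the array's median of all clusters in at least 2 arrays, which left 22063 genes. The RefSeq annotation of assembly GRCm38.p6 served to update these symbols, to place genes beside their neighbours and to give their class.

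The arrays fell into 14 groups by stage, genotype and treatment. limma 3.58.1 in R 4.3.3 fitted 1 model to all arrays with a mean per group, which left 15 residual degrees of freedom and a prior of 3.303. The 22 comparisons were contrasts of these means, each with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p, 2-sided. They were the genotype effect within each stage, each step between consecutive stages in each genotype, the LY3201 effect within each stage and genotype, the differences between genotypes of the LY3201 effects, and averages over stages. The differences between genotypes of the 3 steps were tested in the same model in addition. Every adjusted p of a gene is from limma. Standard errors (SE) are from the same model. Groups held 2 or 3 arrays, and this number limits the precision.

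Lists of marker and pathway genes, 34 in all, were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the lists within a comparison, where at least 5 members had been tested. Each test was repeated with an estimated correlation. Of 638 list tests in the 22 comparisons, 126 passed with the preset correlation and 40 also with the estimated correlation. The lists held 488 genes, of which 439 had a cluster with 1 symbol. The grouping of arrays, the model, the filter, the lists and the rule for naming genes were chosen before the data were examined.

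The rule for naming took, per comparison, Esr1 and Esr2, for genotype also Xist, Tsix and Y-linked genes, and the 6 largest rises and 6 largest falls among called genes whose groups did not overlap (for averages and differences of effects, without the condition on overlap). Predicted genes, small RNAs and receptor gene families were left out of these. It further took up to 4 called members of each list that passed its test or held at least 3 called members. The text uses fewer of them.

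The model was tested on simulated data in which 50 genes were changed at each size. For the LY3201 effect in WT NPC, 36% of genes changed by 0.5 and 88% of genes changed by 1 on the log2 scale were recovered, with 2 false calls. For the difference of the LY3201 effects between genotypes in NPC, 12% and 54% were recovered, and for the averaged genotype effect 96% and 100%, with 18 false calls (8.9% of calls). The simulated noise was independent between genes, had the same spread in every group and held no shift of whole arrays. False calls from such features are therefore not measured by it. Alternatives were no filter, a stricter filter at the 75th percentile, quantile normalization, a trended robust prior, a fit to the compared groups alone, clusters in place of genes, arrays whose titles share a number averaged, and each array left out in turn. Figures were drawn with matplotlib.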

Results

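Expression was measured in 29 arrays at 4 stages: mouse embryonic stem cells kept with LIF (mESC), neural precursor cells grown with FGFb (NPC), midbrain neural precursors patterned with FGF8b and Shh (mDPC), and cells labelled as matured to midbrain neurons (MN). MN thus names the stage, not a measured content of neurons. The mESC stage had 2 arrays per genotype. NPC and mDPC had 2 arrays for each genotype and treatment, where cells received vehicle (called untreated here) or 0.5 nM LY3201 for 4 days. MN had 2 untreated and 2 LY3201 arrays of the wild type (WT), and 3 untreated and 2 LY3201 arrays labelled BERKO. The length of treatment in MN was not given. Values are on a log2 scale. Changes are differences of group means ± SE, with n = 2 arrays per group except for the 3 untreated MN arrays labelled BERKO. The titles of the 2 mESC arrays labelled BERKO share a number, as do those of the 2 NPC WT arrays with LY3201; the labels do not say whether these come from 1 culture, so either group could hold 1 biological replicate.

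Esr2, the gene that the BERKO label names as lost, had the higher signal in every array with that label. It lay between 3.8 and 4.46 in the 15 arrays labelled BERKO and between 3.21 and 3.47 in the 14 arrays labelled WT, so the measured direction went against the label. The difference was 0.71 ± 0.13 in mESC (4.08 against 3.37, adjusted p = 0.00209), 0.99 ± 0.13 in NPC (adjusted p = 1.39e-05), 0.83 ± 0.13 in mDPC (adjusted p = 8.17e-05) and 0.97 ± 0.11 in MN (adjusted p = 2.99e-06). All of these levels were low, near those of the negative controls, whose medians per array ran from 3.747 to 4.245. Every WT level lay below the lowest of these medians and below every array's median of all clusters (at least 3.519). Esr2 thus passed the filter only through arrays labelled BERKO, and its signal in WT was not told from background. The deleted part of Esr2 was not in the labels. WT and BERKO therefore name the labels throughout, and each direction between them is that of the labels as given. Esr1, the related receptor ERα, passed the test between genotypes in MN alone of the 4 stages, with a change of -0.32 ± 0.08 (adjusted p = 0.00853). The X-inactivation transcript Xist lay between 3.46 and 4.58 and the Y-linked genes Eif2s3y, Kdm5d and Uty between 2.98 and 3.71. Xist passed in MN alone (-0.23 ± 0.08, adjusted p = 0.0342), and all 3 of these Y-linked genes lay below the filter.

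**Figure D1:**
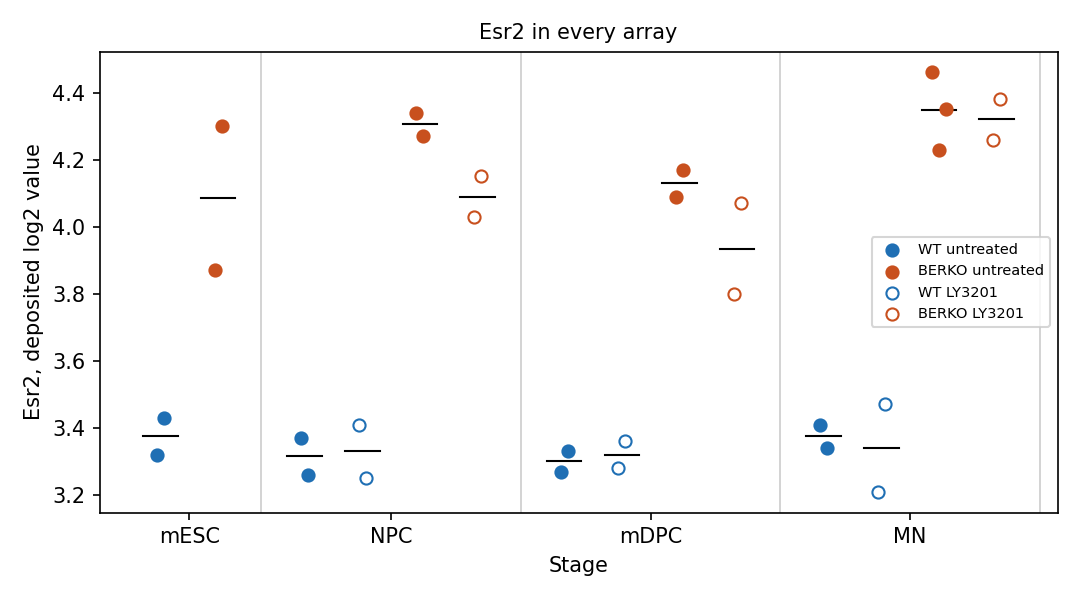
Esr2 signal (log2) in each array by stage and genotype label, with untreated arrays filled, LY3201 arrays open and a line at each group mean. The 15 arrays labelled BERKO lie between 3.8 and 4.46, all above the 14 arrays labelled WT.

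The array medians lay between 3.52 and 3.74. Replicates of a group had Pearson r between 0.9944 and 0.9985 across genes, which are not independent replicates, and SDs of their differences between 0.182 and 0.354. The first principal component held 59% of the variance and the next 24.6%. The largest SDs belonged to the WT pairs of MN, 0.346 and 0.354. As an example, the synaptic gene Snap25 was 6.36 and 9.62 in the 2 untreated WT arrays of MN and 5.89 and 7.61 in the 2 LY3201 arrays, against 4.81 to 4.98 in the 5 arrays labelled BERKO. Of the markers of the dopaminergic midbrain fate, Nr4a2 lay between 5.26 and 6.57 over all arrays, above the medians of the negative controls but below their 95th percentile, which ran from 6.632 to 7.661 by array. Foxa2 (3.99 to 4.58), Lmx1a (3.26 to 3.81) and Slc6a3 (3.38 to 3.84) lay near those medians. Th, the rate-limiting enzyme of dopamine synthesis, lay between 3.19 and 3.57 and Pitx3 between 2.95 and 3.42, both below the filter in these arrays. Of the dopaminergic and floor plate lists, Aldh1a1 reached 13.96 and Gfra1 10.8, above that percentile. Ddc (at most 7.2), Shh (7.21) and En2 (7.11) reached its range, and the other tested members stayed below it. Levels below that percentile were not clearly told from background, so a change between a level above it and one below it is a lower bound. Dppa3 (at most 5.83) lay below it in every array. So did Tap1, Tap2, Psmb8 and Psmb9 of MHC class I presentation (at most 5.49), and Isg15, Irf7, Oasl2, Oas1a and Rsad2 of the interferon list (at most 6.43). In the Hox list, only Hoxa2, Hoxa5, Hoxb6, Hoxb8, Hoxc6, Hoxc8 and Hoxc9 exceeded 6.35 in any array, so the other members lay below it too.

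The steps between stages in WT arrays show how the differentiation ran. From mESC to NPC, genes of radial glia and neural precursors rose: Fabp7 by 14.16 ± 0.15 (19.35 against 5.2, the latter in the range of the negative controls), Sparcl1 by 13.74 ± 0.15 and Ptn by 13.46 ± 0.13. Pluripotency genes fell, with Dppa5a at -15.22 ± 0.14 (4.15 against 19.37, the first near the medians of the negative controls, so a lower bound), Tdgf1 at -12.75 ± 0.18 and Nanog at -11.87 ± 0.13. Of 23 pluripotency genes, 0 were higher and 22 lower (camera adjusted p = 1.83e-15). Of neural progenitor genes such as Nes (7.21 ± 0.22), 14 of 17 were higher and 0 lower, and of astrocyte genes such as Sox9 (9.78 ± 0.12), 15 of 17 were higher and 1 lower. Notch pathway genes such as Hey1 (6.41 ± 0.19) were higher for 12 of 15, and Hox and other hindbrain or spinal genes such as Hoxa5 (4.79 ± 0.24) for 16 of 18, with 1 lower in each list. Adjusted over the list alone these counts were the same, except 2 lower astrocyte genes and 13 higher and 2 lower Notch genes. All of these calls held with an estimated correlation. Axon guidance genes (28 of 33 higher, 2 lower), proliferation genes (26 of 29 lower, 1 higher) and matrix genes (16 of 21 higher, 5 lower) passed with the preset correlation, and had adjusted p = 0.0664, 0.0857 and 0.0857 with an estimated correlation. In all, 6159 genes were higher and 7713 lower.

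From NPC to mDPC in WT arrays, the cell cycle programme fell and astrocyte genes rose. All 29 proliferation genes were lower over all genes and adjusted over the list alone, among them Mki67 (-7.11 ± 0.2), Plk1 (-6.18 ± 0.16) and Top2a (-5.94 ± 0.12), with camera adjusted p = 1.06e-39. Gfap, the intermediate filament of astrocytes, rose by 7.45 ± 0.22 (16.53 against 9.08), Thrsp by 6.16 ± 0.29 and Agt by 6.04 ± 0.2, and 12 of 17 astrocyte genes were higher and 1 lower (14 and 1 adjusted over the list alone). Cholesterol synthesis genes were lower for 10 of 11, with Fdps at -3.03 ± 0.14, and Notch genes for 10 of 15 with 1 higher, both counts the same adjusted over the list alone. Matrix genes were lower for 14 of 21 with 2 higher (14 and 3 adjusted over the list alone), and Dcn, a collagen-binding proteoglycan, fell by 5.53 (SE 0.22). These calls held with an estimated correlation, with adjusted p from 0.0026 for proliferation to 0.0366 for matrix. Mesoderm and mesenchyme genes (7 of 10 lower, 1 higher) had adjusted p = 0.0553 with an estimated correlation. In all, 3226 genes were higher and 3490 lower, and after quantile normalization 3374 and 3334. Without untreated mDPC array 2 they were 2641 and 2572.

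From mDPC to MN in WT arrays, the largest rises were those of Elobl by 14.45 ± 0.33, Fam216b by 11.37 ± 0.19, Ecrg4 by 10.02 ± 0.24, Serping1, the inhibitor of complement C1, by 9.68 ± 0.18, and the complement gene C4b by 9.12 ± 0.11. The myelin genes Mobp (7.67 ± 0.3), Mag (5.4 ± 0.29) and Mog (3.84 ± 0.27) rose, and Stmn2, of growing axons, rose by 6.21 ± 0.64. The largest fall was that of the secreted neural protein gene Nell2 (-7.35 ± 0.19). Proliferation genes were higher again for 22 of 29 with 0 lower, as Mki67 (4.07 ± 0.2), and interferon response genes for 10 of 13 with 0 lower, both counts the same adjusted over the list alone. No list call held with an estimated correlation, with adjusted p = 0.11 for proliferation and 0.249 for interferon response. In all, 3962 genes were higher and 5301 lower. Among changes of more than 2-fold the majority was higher, with 1642 higher and 935 lower. Pan-neuronal genes were higher for 8 of 19 and lower for 3 (8 and 4 adjusted over the list alone, camera adjusted p = 0.0992). The means of these 19 genes in the 2 untreated WT arrays were 6.9 and 8.33, and those of the 17 astrocyte genes 12.22 and 12.07. Means of different lists do not give shares of cells, so effects in MN are not read as effects in neurons.

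The steps of the arrays labelled BERKO resembled those of WT. Changes of the 2 genotypes correlated across genes with r = 0.959 for mESC to NPC, 0.822 for NPC to mDPC and 0.83 for mDPC to MN. From mESC to NPC, 5254 genes were higher in both (1704.2 expected by chance) and 74 moved in opposite directions; the pluripotency genes fell together again (22 of 23, Nanog -12.43 ± 0.13), and Ptn rose by 13.9 ± 0.13. Proliferation genes fell for all 29 members from NPC to mDPC (Mki67 -10.93 ± 0.2, Top2a -8.99 ± 0.12) and rose for all 29 from mDPC to MN (Mki67 7.78 ± 0.18), both with an estimated correlation as well (adjusted p = 0.00207 and 0.03). From mDPC to MN, C4b rose by 10.49 ± 0.1, the acute-phase gene Serpina3n by 10.33 ± 0.18, the interferon-induced Ifit3 by 5.9 ± 0.22 and the MHC class I gene H2-K1 by 2.4 ± 0.08. There, 7 of 8 MHC class I genes and 12 of 13 interferon genes were higher with 0 lower, the same counts adjusted over the list alone, with adjusted p = 0.038 and 0.144 with an estimated correlation. Without untreated MN BERKO array 1, the first was 0.0565. The numbers of genes higher and lower were 6105 and 7913, 3645 and 4173, and 4432 and 6797 for the 3 steps. From NPC to mDPC they were 4287 and 3388 after quantile normalization. For the last step the median of all tested genes was -0.145, and -0.059 after quantile normalization. Among changes of more than 2-fold in that step, 1897 genes were higher and 1065 lower.

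Tests of the difference between the genotypes' steps called 2119, 1914 and 2749 genes. From mESC to NPC, 9 of 18 Hox genes differed downwards and 1 upwards in the arrays labelled BERKO relative to WT, and 5 of 10 mesoderm genes downwards (7 with 1 upwards adjusted over the list alone), while 10 of 11 cholesterol synthesis genes differed upwards. These list calls held with an estimated correlation (adjusted p = 0.000495, 0.0277 and 0.0255), as did the call of matrix genes (9 of 21 downwards and 3 upwards, 9 and 4 adjusted over the list alone, adjusted p = 0.0444). From NPC to mDPC, 9 of 21 matrix genes differed upwards and 1 downwards (9 and 2 adjusted over the list alone) and 4 of 10 mesoderm genes differed upwards (6 with 1 downwards adjusted over the list alone), each with adjusted p = 0.0422 with an estimated correlation. The fall of proliferation genes was larger in the arrays labelled BERKO for 25 of 29 (28 adjusted over the list alone, median difference -1.459, adjusted p = 0.00232 with an estimated correlation). From mDPC to MN, 25 of 29 of them differed upwards (27 adjusted over the list alone, median 1.337, adjusted p = 0.00575 with an estimated correlation), and 6 of 14 genes of the integrated stress response differed downwards with 0 upwards (7 adjusted over the list alone). Notch genes differed upwards for 7 of 15 with 1 downwards under both adjustments, mesoderm genes downwards for 6 of 10 (7 with 1 upwards adjusted over the list alone), and MHC class I genes upwards for 3 of 8 (6 adjusted over the list alone). These 4 lists each had adjusted p = 0.0304 with an estimated correlation. Consecutive steps share the arrays of the stage between them, which enter with opposite sign, so opposite directions in consecutive steps are partly built in and were not read as a turn. The totals were 1318 from mESC to NPC and 1204 from NPC to mDPC without untreated WT array 1 of NPC, and 1617 from mDPC to MN in a fit to the compared groups alone. After quantile normalization the majority turned in the first 2 steps, with 999 upwards and 1009 downwards, and 1047 and 820.

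Genotype was first compared in the undifferentiated cells. In mESC labelled BERKO, Dppa3, a maternal factor and marker of naive pluripotency, was higher by 1.51 ± 0.15 (5.71 against 4.2, adjusted p = 8.45e-06), Klhl13 by 1.15 ± 0.09 and the X-linked homeobox gene Rhox5 by 1.08 ± 0.25. Both Dppa3 levels lay below the upper percentile of the negative controls (at least 7.346 in mESC). They were thus not clearly told from background. The largest rise was that of the mitochondrial transfer RNA mt-Tk (2.51 ± 0.59). The cytochrome P450 gene Cyp2b23 fell by 2.64 (SE 0.22, 6.65 against 9.29, adjusted p = 1.11e-06), Porcn, needed for secretion of Wnt proteins, by 1.67 (SE 0.11, adjusted p = 1.63e-07), and the deacetylase Hdac6 by 1.54 (SE 0.14). Of 23 pluripotency genes, Dppa3, Gdf3 (0.49 ± 0.12) and Dppa4 (0.35 ± 0.09) were higher. The imprinted genes Impact (-0.99 ± 0.11), Peg10 (-0.79 ± 0.21) and Plagl1 (-0.59 ± 0.1) were lower, 3 of 15 members with 0 higher (3 and 1 adjusted over the list alone, camera adjusted p = 0.0968), and no list passed its test. In all, 370 genes were higher and 559 lower, 23 and 49 of them at least 2-fold. This total of 929 was 448 without WT array 1, 422 without WT array 2 and 368 without BERKO array 1 of mESC; it was 157 in a fit to the 2 compared groups alone and 335 with same-number arrays averaged.

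In NPC, proliferation and cholesterol synthesis genes were higher in the arrays labelled BERKO, and matrix, mesenchymal and Hox genes were lower. The glial connexin Gjc3 was higher by 4.66 ± 0.21 (14.46 against 9.81), Mageb16 by 4.81 ± 0.17, the metabotropic glutamate receptor Grm3 by 4.13 ± 0.18 and the AMPA receptor subunit Gria4 by 3.07 ± 0.13. Dcn fell by 4.87 (SE 0.22, 6.06 against 10.93, adjusted p = 1.58e-11), Apod by 4.06 (SE 0.25), the matrix protease Mmp2 by 3.78 (SE 0.1) and Bgn by 3.66 (SE 0.15). Matrix genes were lower for 11 of 21 and higher for 3 (13 and 6 adjusted over the list alone), and mesoderm and mesenchyme genes, such as Col3a1 (-2.86 ± 0.18), lower for 6 of 10 and higher for 1 (7 and 1 adjusted over the list alone). Hox genes of the trunk fell, with Hoxb6 at -2.28 ± 0.15 and Hoxc8 at -2.22 ± 0.25, 10 of 18 members lower and 0 higher under both adjustments. Of this list, only Hoxa2, Hoxa5, Hoxc8 and Hoxc9 exceeded 6.99 in any array. The upper percentile of the negative controls was at least 7.287 in untreated NPC arrays. Levels of the other members, Hoxb6 included, were therefore not clearly told from background. Proliferation genes such as Aurkb (1.03 ± 0.1) and Mki67 (1.01 ± 0.2) were higher for 23 of 29 and lower for 1 (24 and 1 adjusted over the list alone), and cholesterol synthesis genes such as Fdps (1.34 ± 0.14) and Idi1 (1 ± 0.13) for 10 of 11 under both.

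These 5 list calls in NPC held with an estimated correlation, with adjusted p = 0.0168 for matrix, 0.0168 for mesoderm and mesenchyme, 0.000127 for Hox, 0.0313 for proliferation and 0.0223 for cholesterol synthesis. Oligodendrocyte genes were higher for 4 of 13, among them Gpr17 (2.59 ± 0.3) and Olig2 (2.13 ± 0.18), with 0 lower. Axon guidance and migration genes went both ways, 6 of 33 higher and 10 lower (6 and 12 adjusted over the list alone), with the chemokine receptor Cxcr4 at -2.56 ± 0.17 and the netrin receptor Dcc at 1.67 ± 0.12. The oligodendrocyte and axon guidance calls each had adjusted p = 0.468 with an estimated correlation. Floor plate genes, 3 of 12 lower and 0 higher, had 0.108, and imprinted genes, 5 of 15 lower and 3 higher (7 and 3 adjusted over the list alone), 0.396. In all, 2334 genes were higher and 1120 lower. The total of 3454 was 1898 without untreated WT array 1 and 2019 without untreated BERKO array 2 of NPC. After quantile normalization 1316 were higher and 1650 lower, so the majority of calls were lower under that scaling.

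In mDPC, stress response and cholesterol synthesis genes were higher in the arrays labelled BERKO, and proliferation, Notch and Hox genes were lower. The GABA-A receptor subunits Gabra4 and Gabrb1 were higher by 5.65 ± 0.22 and 5.4 ± 0.15, and Luzp2 by 5.87 ± 0.17. The falls were led by the protease inhibitor A2m (-5.34 ± 0.14), the stem cell surface gene Prom1 (-4.79 ± 0.13) and Hoxc8 (-4.64 ± 0.25). Proliferation genes were lower for 20 of 29 and higher for 0 (22 and 0 adjusted over the list alone, camera adjusted p = 4.54e-23), with Mki67 at -2.82 ± 0.2 and Top2a at -2.24 ± 0.12, the opposite of their direction in NPC. Of the Notch genes 6 of 15 were lower (7 adjusted over the list alone) and 0 higher, among them Notch2 (-1.66 ± 0.18) and the ligand Dll4 (-1.35 ± 0.16). Of 14 genes of the integrated stress response 6 were higher (8 adjusted over the list alone) and 0 lower, among them asparagine synthetase Asns (2.59 ± 0.13) and Chac1 (1.51 ± 0.17). Cholesterol synthesis genes such as Idi1 (1.3 ± 0.13) were higher for 9 of 11 (10 adjusted over the list alone), and Hox genes lower for 9 of 18 and higher for 3 (10 and 3 adjusted over the list alone).

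These 5 list calls in mDPC held with an estimated correlation, with adjusted p = 0.016 for proliferation, 0.0208 for Notch, 0.045 for the stress response, 0.0416 for cholesterol synthesis and 0.00149 for Hox. The stress response had 0.0546 without untreated WT array 1 and 0.0602 without untreated WT array 2, and cholesterol synthesis 0.0518 without untreated WT array 2 and 0.0607 without untreated BERKO array 2. Oligodendrocyte genes were higher for 8 of 13 and lower for 0 under both adjustments, among them Olig2 (2.27 ± 0.18) and Sox10 (1.53 ± 0.18), with adjusted p = 0.12 with an estimated correlation. Axon guidance and migration genes were lower for 15 of 33 and higher for 3 (16 and 3 adjusted over the list alone), among them Reln, which guides migrating neurons (-3.99 ± 0.24), and Cxcr4 (-3.4 ± 0.17), also with 0.12. The astrocyte genes Gfap (-3.23 ± 0.22) and S100b (2.19 ± 0.26) moved in opposite directions, and the cell cycle inhibitor Cdkn1a was higher by 1.57 ± 0.21, where p53 targets were higher for 3 of 10 and lower for 1 (5 and 1 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). In all, 1877 genes were higher and 1174 lower, and the total of 3051 was 1852 without untreated BERKO array 1 of mDPC.

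In MN, with 3 arrays labelled BERKO against 2 of WT, interferon response and MHC class I genes were higher in the arrays labelled BERKO. Ifit3 was higher by 3.56 ± 0.22, Ifit1 by 3.32 ± 0.33 and Bst2 by 2.95 ± 0.22, and 11 of 13 interferon genes were higher and 0 lower (camera adjusted p = 9.88e-13). H2-K1 was higher by 1.65 ± 0.08, H2-D1 by 1.24 ± 0.09 and B2m, the shared light chain, by 0.99 ± 0.15, with 7 of 8 genes of MHC class I presentation higher and 0 lower (adjusted p = 3.08e-07). Of these 8, Tap1, Tap2, Psmb8 and Psmb9 did not exceed 5.49 in any array. Of the 13 interferon genes, Isg15, Irf7, Oasl2, Oas1a and Rsad2 did not exceed 6.43 in any array. The upper percentile of the negative controls was at least 6.632 in MN, so the levels of these genes of both lists were not clearly told from background. Dcn (-5.65 ± 0.2) and Apod (-5.55 ± 0.23) were lower. Of 10 mesoderm and mesenchyme genes 8 were lower, among them Postn (-3.43 ± 0.13), and 1 higher. Hox genes were lower for 9 of 18, with Hoxc8 at -3.05 ± 0.23, and higher for 2 (9 and 3 adjusted over the list alone). The other counts of this paragraph were the same adjusted over the list alone. With an estimated correlation the calls held, with adjusted p = 0.044 for interferon response, 0.0135 for MHC class I, 0.0218 for mesoderm and 0.013 for Hox. The interferon call had 0.0649 without untreated WT array 2 and 0.0612 without both WT arrays of MN that stood apart (array 2 of each treatment).

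In MN, pan-neuronal genes were lower for 15 of 19 and higher for 0 (16 and 0 adjusted over the list alone), with Snap25 at -3.12 ± 0.57, the neurofilament genes Ina at -2.72 ± 0.57 and Nefl at -2.38 ± 0.57, and adjusted p = 0.267 with an estimated correlation. Their mean was 6.9 and 8.33 in the 2 untreated WT arrays and 6.44, 6.59 and 6.6 in the 3 arrays labelled BERKO. Ina had 7.89 and 10.66 in the untreated WT arrays against 6.43 to 6.76 in those labelled BERKO, and Nefl 4.72 and 7.75 against 3.8 to 3.89, so the size of these changes rested largely on WT array 2. Without both WT arrays that stood apart, 7 were lower and 1 higher and the median moved from -0.791 to -0.26, with adjusted p = 0.0172 with an estimated correlation. Proliferation genes were higher for 23 of 29 and lower for 0 (25 and 0 adjusted over the list alone), among them Top2a (1.24 ± 0.11) and Plk1 (1.17 ± 0.15), with adjusted p = 0.0518 with an estimated correlation, and 0.047 without both arrays. Axon guidance and migration genes were lower for 20 of 33 and higher for 3 (21 and 6 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation).

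In MN, imprinted genes were lower for 8 of 15, among them Peg3 (-2.57 ± 0.28), Peg10 (-2.49 ± 0.19) and Ndn (-2.22 ± 0.43), and higher for 2 (9 and 2 adjusted over the list alone, adjusted p = 0.0528 with an estimated correlation). Ndn was 11.28 and 13.86 in the 2 untreated WT arrays, against 10.23 to 10.43 in the arrays labelled BERKO, and without both WT arrays that stood apart the median of the list moved from -0.599 to -0.11, with 7 lower and 3 higher (adjusted p = 0.0227 with an estimated correlation). The myelin genes Mobp (-2.36 ± 0.27), Mog (-1.99 ± 0.24) and Mag (-1.41 ± 0.26) were lower, while Olig2, a transcription factor of the same lineage, was higher by 1.5 ± 0.16; of 13 oligodendrocyte genes 3 were higher and 4 lower (5 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.807). Cholesterol synthesis genes were higher for 7 of 11 and lower for 0 (8 and 0 adjusted over the list alone, adjusted p = 0.189 with an estimated correlation). Of 8 estrogen-responsive genes tested, Myb was higher (2.43 ± 0.13) and Igfbp4 lower (-1.44 ± 0.15), and the list did not pass (2 higher, 1 lower, camera adjusted p = 0.996). In all, 2972 genes were higher and 1612 lower; the total of 4584 was 2297 in a fit to the compared groups alone.

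**Figure D2:**
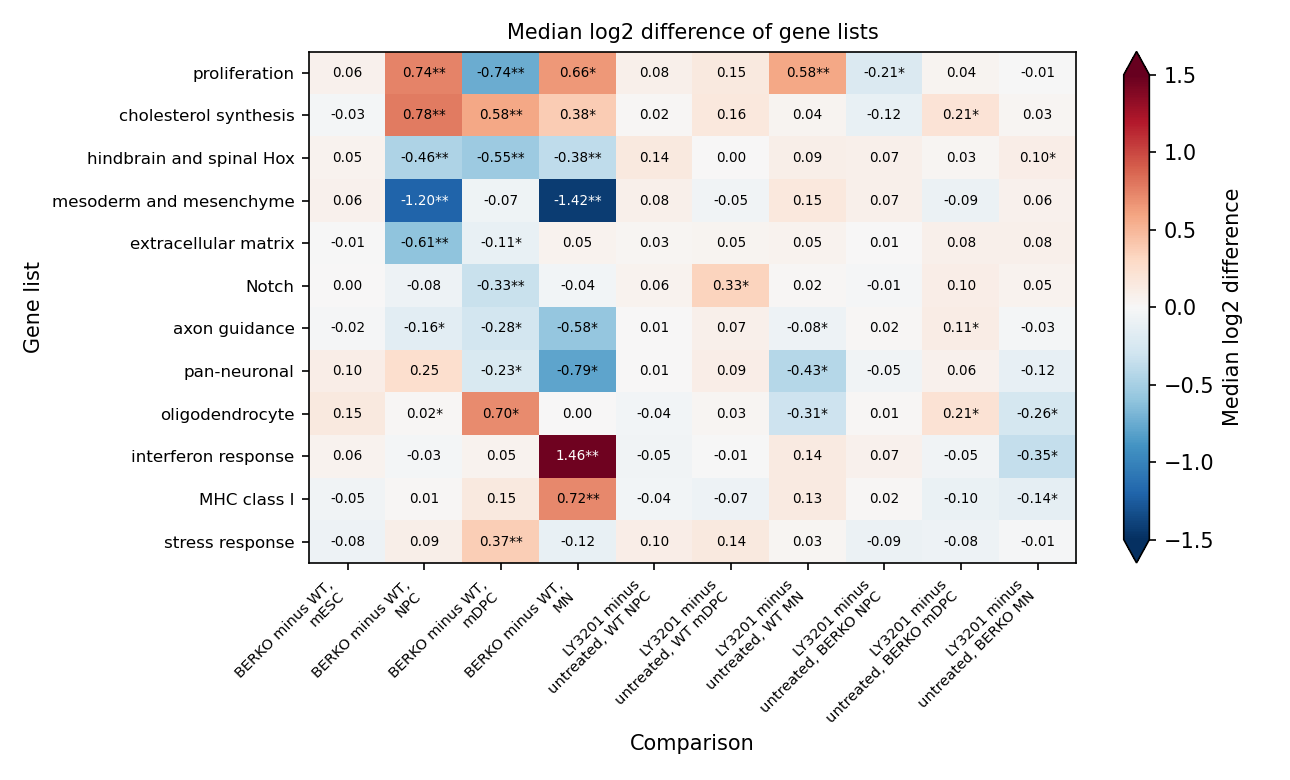
Median log2 change of 12 gene lists (vertical) in 10 comparisons (horizontal), by colour; one star marks a camera adjusted p under 0.05 with the preset correlation and a double star also with the estimated correlation. Proliferation genes were higher in NPC, lower in mDPC (20 of 29 genes) and higher in MN (23 of 29, a call lost with the estimated correlation, adjusted p = 0.0518) in arrays labelled BERKO, and the Hox list was lower in these 3 stages.

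**Figure D3:**
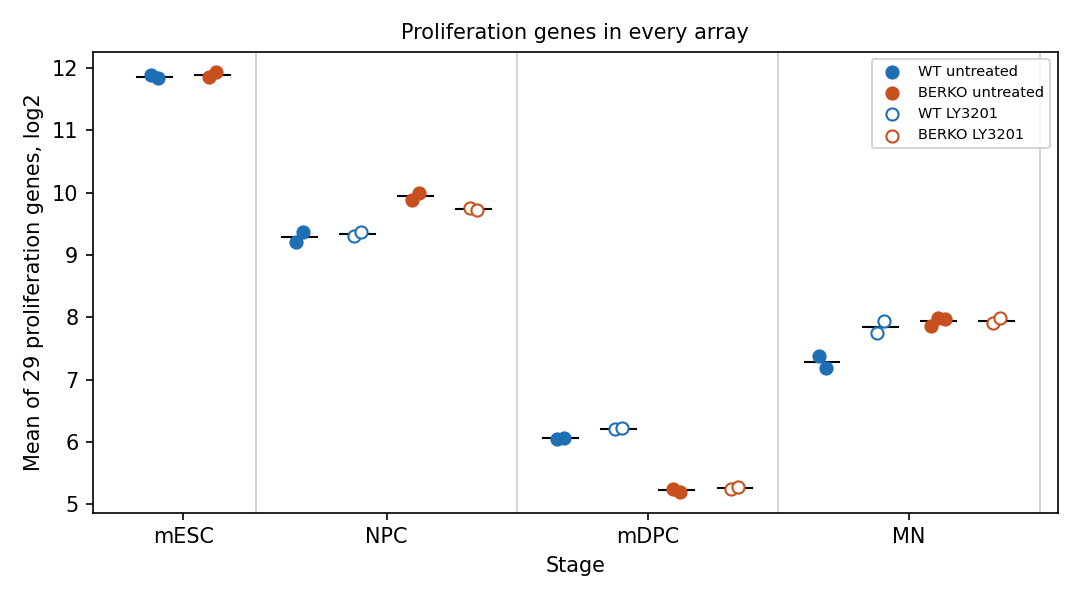
Mean log2 signal of 29 proliferation genes in each array by stage and genotype, with untreated arrays filled, LY3201 arrays open and a line at each group mean. In MN the untreated WT arrays lie at 7.19 and 7.37, the WT arrays with LY3201 at 7.74 and 7.94, and the untreated arrays labelled BERKO between 7.86 and 7.99.

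The genotype comparisons of the stages use no array in common. NPC and mDPC shared 654 higher genes (198.6 expected by chance) and 399 lower genes (59.6 expected), with r = 0.454 across genes. NPC and MN shared 794 and 324 (314.4 and 81.8 expected), and mDPC and MN 848 and 351 (252.8 and 85.8 expected). Across genes, r was 0.133 for NPC and MN and 0.243 for mDPC and MN. The mESC effects had r = 0.002 with those in NPC, -0.002 with those in mDPC and 0.232 with those in MN. Their called genes shared 87 higher and 99 lower with NPC (39.1 and 28.4 expected), 31 and 72 with mDPC (31.5 and 29.7 expected), and 41 and 82 with MN (49.8 and 40.8 expected). Called in opposite directions were 92 genes with NPC, 91 with mDPC and 103 with MN (77.9, 67.2 and 102.3 expected). Averaged over stages and treatments, 3752 genes were higher and 2833 lower in arrays labelled BERKO, led by Mageb16 (4.08 ± 0.07), Luzp2 (4.05 ± 0.06), Gabra4 (3.54 ± 0.08) and Gabrb1 (3.28 ± 0.06), and by Apod (-3.51 ± 0.09), Bgn (-3.49 ± 0.06) and Hoxc8 (-3.13 ± 0.09). The averaged calls of Hox genes (11 of 18 lower, 4 higher), mesoderm genes (8 of 10 lower, 1 higher) and cholesterol synthesis genes (11 of 11 higher) held with an estimated correlation, with adjusted p = 0.0034, 0.0307 and 0.0307. Adjusted over the list alone, the Hox counts were 12 and 5 and the others were the same. Interferon genes, 11 of 13 higher on average, had adjusted p = 0.184 with an estimated correlation.

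Genes called in the same direction at all 4 stages numbered 11 higher (0.45 expected by chance) and 34 lower (0.11 expected). The higher ones included Esr2 and the lactate dehydrogenase gene Ldhb, and the lower ones the axon guidance gene Ntn1 and the imprinted genes Peg10, Plagl1 and Impact, all picked here after their values were seen. Of the 34 lower genes, 17 were neighbours on the X chromosome. In a stretch of 41 tested protein-coding genes from Btbd35f16 to Ssxb5, found in the mESC arrays after the values were seen, 21 genes were lower in mESC, 22 in NPC, 22 in mDPC and 27 in MN, and 1, 0, 0 and 0 were higher. The stretch holds Porcn (-1.67, -0.96, -1.22 and -1.54 in the 4 stages), Hdac6 (-1.54, -0.88, -1.12 and -0.85) and Otud5 (-0.82, -1.26, -1.24 and -1.07). The median change of its 26 brighter genes was -0.82, -0.83, -0.8 and -0.88, while the median of the 515 other tested X-linked genes was 0.07, 0.01, 0.03 and -0.01.

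**Figure D4:**
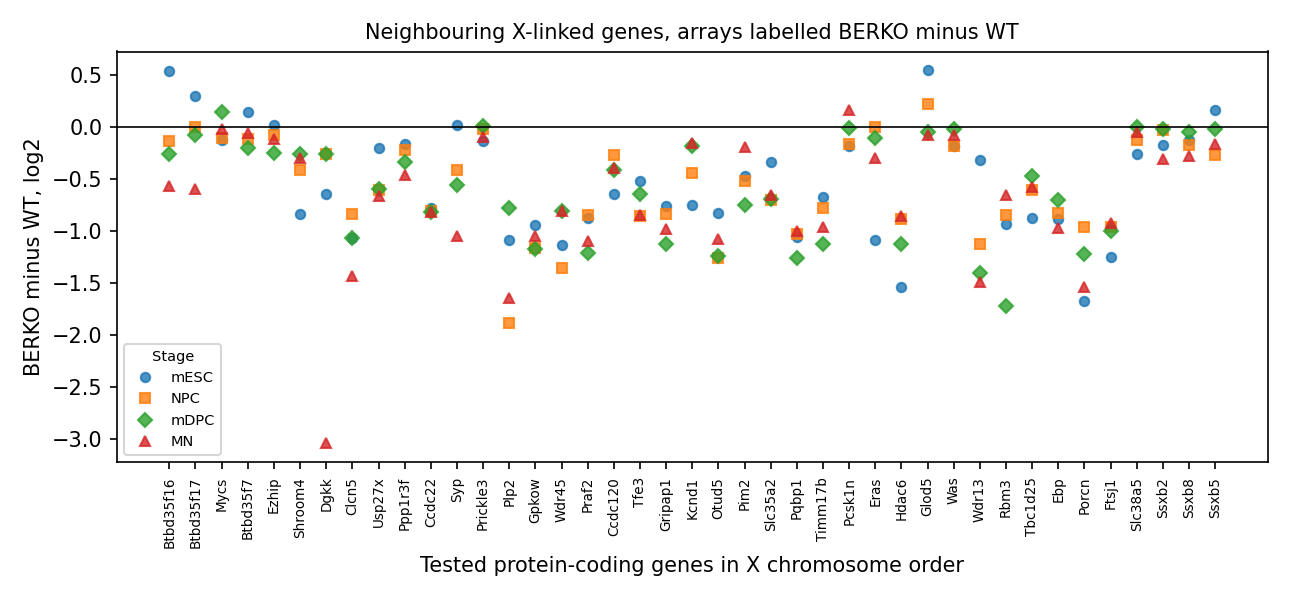
Genotype change (log2, arrays labelled BERKO minus WT) of 41 neighbouring X-linked genes from Btbd35f16 to Ssxb5 in gene order, with one symbol per stage. The medians over the 41 genes are -0.64 in mESC, -0.52 in NPC, -0.55 in mDPC and -0.65 in MN.

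LY3201 tests the response to an ERβ agonist, though Esr2 was not told from background in the WT arrays. In WT NPC, 1 gene passed, the predicted gene Gm25636 (1.14, adjusted p = 0.015), named after its values were seen; 2204 genes had an unadjusted p under 0.05 in limma. None was called without untreated array 1, untreated array 2 or LY3201 array 1 of WT NPC (0 genes each), and 3 were without LY3201 array 2. In WT mDPC, the histone genes Hist1h2aj (1.31 ± 0.24) and H2ac10 (1.28 ± 0.22), the phosphatase gene Dusp1 (0.99 ± 0.16, 7.14 against 6.15, adjusted p = 0.0459), Brinp2 (0.71 ± 0.13) and the Notch target Hes5 (0.68 ± 0.12, 7.2 against 6.52, adjusted p = 0.0459) were higher. Of 15 Notch genes, Hes5 alone was higher over all genes and 6 were adjusted over the list alone, with camera adjusted p = 0.0046 and adjusted p = 0.171 with an estimated correlation. In all, 8 genes were higher and 6 lower. Other settings left few calls: 1 without a filter, 1 after quantile normalization, 3 with same-number arrays averaged and 0 in a fit to the compared groups alone. The total of 14 was 33 and 1 (lower) without untreated arrays 1 and 2, and 0 without LY3201 array 1 or 2 of WT mDPC, with 2800 genes at an unadjusted p under 0.05 in limma.

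In WT MN, proliferation genes were higher with LY3201. Ccnb2 was higher by 1.05 ± 0.21, Bub1 by 0.94 ± 0.15, Kif20a by 0.93 ± 0.14 and Mcm2 by 0.91 ± 0.13, and 18 of 29 proliferation genes were higher and 0 lower (23 and 0 adjusted over the list alone, camera adjusted p = 1.95e-25). The call held with an estimated correlation (adjusted p = 0.0211), with a median change of 0.576. Without untreated WT array 2 the median was 0.43 (5 higher, adjusted p = 0.0554 with an estimated correlation), without LY3201 WT array 2 it was 0.54 (4 higher, 0.0767), and without both it was 0.4 (0 higher, 0.0658; camera adjusted p = 6.53e-10). The myelin genes Cldn11 (-1.63 ± 0.31) and Mal (-1.54 ± 0.33) and the oligodendrocyte precursor gene Gpr17 (-1.51 ± 0.3) fell, and 2 of 13 oligodendrocyte genes were lower (3 adjusted over the list alone, adjusted p = 0.249 with an estimated correlation). The largest rises were Hsp25-ps1 (1.51 ± 0.2), S100a4 (1.32 ± 0.29) and Scarna6 (1.25 ± 0.25). Ddc, which makes dopamine from L-DOPA, was lower by a change of -0.6 ± 0.15, the 1 called member of 12 dopaminergic genes (adjusted p = 0.488 with an estimated correlation). That call was lost without both arrays, where 1 other member was higher and 0 lower. The mean of the pan-neuronal genes, of which limma called 0 (0 higher and 1 lower adjusted over the list alone, adjusted p = 0.628 with an estimated correlation), was 6.75 and 7.63 in the LY3201 arrays against 6.9 and 8.33 in the untreated arrays.

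In all, 343 genes were higher and 60 lower with LY3201 in WT MN. Without untreated array 1 the majority turned, with 201 higher and 309 lower, and 183 genes shared with the 403. The total of 403 was 138 without untreated array 2, 652 without LY3201 array 1, 109 without LY3201 array 2 and 100 without both arrays that stood apart; it was 245 after quantile normalization and 0 in a fit to the compared groups alone. The 2 untreated WT arrays of MN serve both in this comparison and in the genotype comparison in MN. Of 8 estrogen-responsive genes, 0 were called in NPC, 0 in mDPC and 1 in MN, which was Greb1 (0.39, adjusted p = 0.0083), a classical target of estrogen receptors; its level was low (3.87 to 4.67 over all arrays), and the list's camera adjusted p was 0.488, 0.82 and 0.467.

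In arrays labelled BERKO, LY3201 called 0 genes in NPC with limma, where 1843 had an unadjusted p under 0.05, and 1 gene was called without LY3201 array 2. Proliferation genes there had a median of -0.213 with 0 called (camera adjusted p = 3.31e-06, and 0.79 with an estimated correlation). In mDPC, Tns3, a focal adhesion gene, was higher by 1.02 ± 0.14 (adjusted p = 0.00543), the transferrin receptor Tfrc by 0.91 ± 0.17 and Cyfip2 by 0.89 ± 0.1 (adjusted p = 0.00205), and the folate enzyme gene Aldh1l2 was lower at -0.78 ± 0.14. Cholesterol synthesis genes had a median of 0.209 with 0 called (1 higher adjusted over the list alone, camera adjusted p = 8.16e-07, and 0.298 with an estimated correlation). In all, 13 genes were higher and 12 lower. The total of 25 was 0 and 1 without untreated arrays 1 and 2 and 9 and 7 without LY3201 arrays 1 and 2 of mDPC, and 0 in a fit to the compared groups alone.

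In MN labelled BERKO, Ifit3 fell with LY3201 (-1.42 ± 0.22, 8.84 against 10.26, adjusted p = 0.0107), as did Deup1 (-0.92 ± 0.15) and Cfap126 (-0.81 ± 0.15), genes of motile cilia, and the peptide loading gene Tapbp (-0.54 ± 0.11). The cluster annotated to the gene symbol Cdr1 was higher by 1.25 ± 0.23, and the stress gene Atf3 by 0.59 ± 0.12. Of interferon genes 1 of 13 was lower and 0 higher (6 and 0 adjusted over the list alone, camera adjusted p = 7.39e-06, and 0.428 with an estimated correlation), and of MHC class I genes 1 of 8 (3 adjusted over the list alone, 0.428 with an estimated correlation). In all, 10 genes were higher and 66 lower. The total of 76 was 23, 307 and 17 without untreated arrays 1, 2 and 3, and 16 and 5 without LY3201 arrays 1 and 2; it was 32 after quantile normalization and 0 in a fit to the compared groups alone. Of 8 estrogen-responsive genes, 0 were called in NPC, mDPC or MN labelled BERKO (camera adjusted p = 0.618, 0.586 and 0.428).

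The LY3201 effects of the genotypes were compared directly. In MN, 8 genes differed upwards and 131 downwards in the arrays labelled BERKO relative to WT: Ifit3 by -2.08 ± 0.33, the calcium-binding S100a6 by -1.35 ± 0.24, Cdrt4 by 1.32 ± 0.26 and Atf3 by 0.9 ± 0.17. Of 29 proliferation genes 4 differed downwards (22 adjusted over the list alone), among them Kif20a (-0.94 ± 0.19) and Mcm2 (-0.86 ± 0.18), with camera adjusted p = 2.81e-15, and 0.15 with an estimated correlation. In NPC, 1 gene differed upwards and 109 downwards, of which 38 were annotated as protein coding, 35 as pseudogenes, 15 as snoRNAs, 10 as snRNAs and 4 as rRNAs. Among them was Rpl13-ps3 (-1.56 ± 0.27), a pseudogene of an expressed ribosomal protein gene, and probes need not tell such copies apart. In mDPC, limma called 0 genes, with 1845 at an unadjusted p under 0.05, and 8 without untreated WT array 1.

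The counts of these differences rested on single arrays. In NPC the total of 110 was 0 and 25 without untreated WT arrays 1 and 2, 0 and 201 without LY3201 WT arrays 1 and 2, 376 and 0 without untreated BERKO arrays 1 and 2, 0 and 1 without LY3201 BERKO arrays 1 and 2, and 0 after quantile normalization. In MN, 121 genes differed upwards and 117 downwards without untreated WT array 1, so the imbalance rested on that array, and the total of 139 was 238 and 32 without untreated WT arrays 1 and 2, 347 and 18 without LY3201 WT arrays 1 and 2, 260 and 27 without untreated BERKO arrays 2 and 3, 21 and 20 without LY3201 BERKO arrays 1 and 2, and 7 after quantile normalization. Across genes, the LY3201 changes of the 2 genotypes correlated with r = -0.315 in NPC, 0.03 in mDPC and -0.025 in MN.

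Averaged over the 3 neural stages, LY3201 was followed by 1440 higher and 153 lower genes in WT and by 0 higher and 1 lower gene in arrays labelled BERKO, the muscle LIM gene Csrp1 (-0.43 ± 0.05, adjusted p = 0.00259; 3048 genes at an unadjusted p under 0.05 in limma). By class, 52 of 62 rRNA, 169 of 767 snRNA, 56 of 751 snoRNA, 364 of 3286 pseudogene and 746 of 14536 protein-coding entries were higher in WT, and 0, 1, 8, 13 and 96 lower; with quantile normalization 6, 39, 26, 103 and 68 were higher and 0, 0, 3, 7 and 77 lower. Of 1553 lncRNA entries 8 were higher and 15 lower, and 6 and 3 with quantile normalization. The largest WT rises were mmu-mir-6240 (1.35 ± 0.31), Scarna6 (0.96 ± 0.14), Rpl36-ps3 (0.86 ± 0.12) and the linker histone H1f1 (0.86 ± 0.18). Proliferation genes were higher for 15 of 29 (21 adjusted over the list alone), as Ccnb2 (0.57 ± 0.12), with camera adjusted p = 1.43e-10, and 0.46 with an estimated correlation. Hox genes in arrays labelled BERKO had a median of 0.076 with 0 called, with adjusted p = 0.0269 with an estimated correlation. That value was 0.0869 without untreated NPC array 1, 0.143 without LY3201 NPC array 2, 0.072 and 0.0916 without untreated and LY3201 mDPC array 2, and 0.0587 without LY3201 MN array 2. The WT total of 1593 was 371 after quantile normalization (268 higher and 103 lower), with 316 of the genes shared. It was 1003 in a fit to the compared groups alone, 1026 with same-number arrays averaged and 695 without both MN arrays that stood apart. It was 696 and 797 without untreated and LY3201 array 1 of WT NPC, 669 without untreated array 2, 939 and 1026 without LY3201 arrays 1 and 2 of WT mDPC, and 1017 without LY3201 array 2 of WT MN. The BERKO total of 1 was 20 and 24 without untreated array 2 and LY3201 array 1 of mDPC, 15 and 43 without untreated arrays 1 and 2 of MN, and 5 and 2 without LY3201 arrays 1 and 2 of MN.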

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

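The test of splits of the arrays was chosen before its result was seen, and the other tests of the LY3201 effect in WT were chosen after the result was seen.

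The effects of the step between stages differed between genotypes by a direct test for 2119 genes from mESC to NPC, 1914 from NPC to mDPC and 2749 from mDPC to MN. From mESC to NPC, with the change in arrays labelled BERKO given first and that in WT second, Gjc3 differed by 5.06 (10.25 and 5.19), Mageb16 by 4.61 (-0.23 and -4.84), Dcn by -4.93 (2.11 and 7.04) and Apod by -4.05 (3.36 and 7.41). From NPC to mDPC, Dcn differed by 4.22 (-1.31 and -5.53), Gabrb1 by 4.19 (4.63 and 0.44), A2m by -5.29 (-1.67 and 3.62) and Pi15 by -4.53 (-1.95 and 2.58). From mDPC to MN, Susd2 differed by 5.27 (5.82 and 0.56), Padi2 by 5.17 (6.54 and 1.37), Dcn by -5 (-0.39 and 4.61) and Elobl by -4.14 (10.31 and 14.45).

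The effects of LY3201 differed between genotypes by a direct test for 110 genes in NPC and 139 in MN. In MN, in the same order, Cdrt4 differed by 1.32 (0.85 and -0.47), Atf3 by 0.9 (0.59 and -0.31), Ifit3 by -2.08 (-1.42 and 0.66) and S100a6 by -1.35 (-0.24 and 1.11). No group held 4 or more arrays, so no array was tested as an outlier within its group.

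LY3201 called 1593 genes in WT on average and 1 in arrays labelled BERKO. Among 100 splits of the WT arrays within stage the highest other count was 484, which argues against a chance division without excluding it. A shift in scale shared by the arrays of a treatment would set the real split apart too. So would NPC arrays with LY3201 that come from 1 culture. For BERKO 14 of 100 splits called as many, with 16 the highest other, so chance is not excluded there. A difference in scale between arrays, such that bright genes read higher with LY3201 in WT, may account for part of the calls: 1277 ended when every array was given one distribution, and the 1174 higher ones among them moved from a median change of 0.29 to 0.178 (SE 0.07 in both), so they ended because their changes shrank, and how much of them scale explains cannot be told. It is not the whole cause, since 316 calls stayed. The rise of bright genes was not confined to the MN WT arrays that stood apart. The brightest genes (4413 of those tested) had a median change of at least 0.111 in NPC and in mDPC too. It averaged 0.126 over the stages and was 0.007 with one distribution. That scaling removes such a rise whether its cause is technical or biological, so the value of 0.007 decides neither. One distribution removes only a difference in scale of whole arrays, so a technical difference of a class of RNA stays open for the 316 calls. The entries higher in WT with one distribution were 68 protein-coding, 103 pseudogene, 39 snRNA, 26 snoRNA, 6 rRNA and 6 lncRNA. In a direct test the averaged LY3201 changes differed between genotypes for 1729 genes, and for 685 with one distribution. Whether that difference needs ERβ cannot be told apart from other differences between the lines, since line and genotype coincide.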

How the results depend on the processing

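The alternative without both MN WT arrays that stood apart was chosen after seeing the data, as were all alternatives for the differences of the steps between genotypes. Of 1043 called named values, 1014 kept their call without a filter, 976 after quantile normalization and 1041 with a trended robust prior, and all 954 that could be recomputed with the stricter filter did. No value reversed after quantile normalization. The filters and the prior leave the group means unchanged, so no direction could reverse under them. The counts of the 22 comparisons stayed within 1.5 times for 19 without a filter, 18 with the stricter filter, 14 after quantile normalization, 22 with the trended robust prior, 12 in a fit to the compared groups alone, 22 with clusters as features, 15 with same-number arrays averaged and 3 of 6 without both MN WT arrays. No paired analysis was possible because the labels do not pair the arrays. With 1 array left in a group, that array is assumed to vary like the other groups. Signal over background limits low genes such as Esr2: in each array 22.51% to 29.64% of genes lay above the 95th percentile of the negative controls.

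The counts that moved further were as follows, and the cause was not tested except where fewer arrays or genes entered. Without a filter, LY3201 in WT mDPC called 1 gene, and its difference between genotypes 53 in NPC and 91 in MN. With the stricter filter, LY3201 in WT NPC called 8, the difference 265 in NPC and 247 in MN, and the average in BERKO 30. After quantile normalization, LY3201 in WT called 0 in NPC, 1 in mDPC, 245 in MN and 371 on average, in BERKO 32 in MN, and the difference was called for 0 in NPC, 2 in mDPC and 7 in MN. The share of higher genes moved from 67.6% to 44.4% for genotype in NPC, from 85.1% to 64.5% for LY3201 in WT MN and from 90.4% to 72.2% for the WT average. In a fit to the compared groups alone, genotype called 157 in mESC and 2297 in MN, LY3201 in WT 0 in NPC, mDPC and MN and 1003 on average, LY3201 in BERKO 0 in mDPC, MN and on average, and its difference 0 in MN. With same-number arrays averaged, genotype in mESC called 335, LY3201 in WT 0 in NPC, 3 in mDPC and 1026 on average, in BERKO 3 in NPC and 4 on average, and the difference 0 in NPC. Without both MN WT arrays that stood apart, LY3201 in WT MN called 100 (29 shared), the difference in MN 11 (3 shared) and the WT average 695 (553 shared).

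With each array left out in turn, genotype called 368 to 1050 in mESC, 1898 to 2657 in NPC and 1852 to 2447 in mDPC. LY3201 in WT called 0 to 3 in NPC, 0 to 33 in mDPC, 109 to 652 in MN and 669 to 1716 on average. In BERKO it called 0 to 1, 0 to 9, 5 to 307 and 1 to 43. The difference between genotypes called 0 to 376 in NPC, 0 to 8 in mDPC and 18 to 347 in MN. The differences of the steps between genotypes were called for 1318 to 1895 from mESC to NPC and 1204 to 1543 from NPC to mDPC. The other counts moved by less than 1.5 times, among them 2072 to 2605 for the difference of the step from mDPC to MN, which was 1617 in a fit to the compared groups alone.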

Other observations

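The tests of the cilia, small nucleolar RNA, X-linked and Esr2 patterns were chosen after the result was seen, and the test of splits of the arrays was chosen before.

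On a list of 25 genes of motile cilia, written after Deup1 and Cfap126 had been seen, 21 were tested; from mDPC to MN 17 were higher in WT (median 2.42) and 20 in arrays labelled BERKO (median 3.26), with 0 lower, and each list call had adjusted p = 0.0683 with an estimated correlation. Between genotypes in MN, 15 were higher and 1 lower in the arrays labelled BERKO (median 0.79, camera adjusted p = 1.81e-08, and 0.224 with an estimated correlation), so these data leave open whether the list as a whole differed. With LY3201 in MN labelled BERKO the median was -0.3 with 0 called (limma; camera adjusted p = 0.000655, and 0.539 with an estimated correlation).

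Small nucleolar RNAs in the imprinted stretch between Ndn and Ube3a changed strongly. Of 170 tested, 169 rose from mDPC to MN in WT (median 5.61) and 107 in arrays labelled BERKO (median 1.81). Between genotypes in MN, 129 were lower in arrays labelled BERKO (median -3.19), whereas 36 were higher in NPC (median 1.28) and 20 lower in mESC (median -1.58). In mDPC 0 were called in either direction (median 0.9). In NPC, array medians without LY3201 were 6.32 and 6.32 in WT against 7.66 and 7.61 in those labelled BERKO. With LY3201 they were 7.25 and 7.1 against 7.21 and 7.23. Whether the genotype difference changed with LY3201 was not tested for these RNAs as a group. The mESC medians, 5.39 to 7.03, lay below the 95th percentile of the negative controls. So did every NPC median except 7.66 and 7.61, those of the untreated arrays labelled BERKO. The other NPC levels were therefore not clearly told from background. The RNAs are near-identical copies and so not independent. The WT arrays of MN spread widely, with medians of 12.56 and 14.83 untreated and 11.53 and 14.85 with LY3201, against 10.37 to 10.95 in arrays labelled BERKO. Pan-neuronal means were likewise higher in WT array 2 of each treatment, with 6.9 and 8.33 untreated and 6.75 and 7.63 with LY3201. They were 6.42 to 6.6 in arrays labelled BERKO. Whether the RNAs follow the content of neurons was not tested.

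The stretch of 41 neighbouring X-linked genes was lower in the arrays labelled BERKO at every stage, and in NPC, mDPC and MN 0 of 14086 other runs of 20 genes were as low, a length chosen after runs of 15 and 20 had both been tried; with 15 genes, 0 were as low in NPC and mDPC but 9 in MN. A chance run is thus excluded for NPC and mDPC under both lengths, and a difference of the whole X chromosome by the median of 0.01 of the other X-linked genes, against -0.58 in the stretch. A difference in copy number or another difference between the lines in this stretch cannot be told apart from a response to loss of ERβ, because line and genotype coincide and both predict what was seen, at least 20 of the 26 brighter genes lower at each stage. LY3201 moved the brighter genes in WT by a median of 0.07, which decides neither.

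The higher Esr2 signal in the arrays labelled BERKO is not explained by single exchanged labels, since 0 arrays labelled BERKO lay at or below the highest WT array. Nor is it explained by a general rise of dim genes: 3501 other genes of its level had a median change of -0.015, and 0 of them rose as much. A cluster that reads parts of the gene outside the deleted part cannot be told apart from other causes, since the deleted part is not in the labels; the Esr2 level in arrays labelled BERKO lay 0.24 above the median of the negative controls. Some genes further along the chromosome were also higher on average (1700086L19Rik 0.73, Dbpht2 0.75, Rhoj 0.44, Kcnh5 0.38), though not in mESC (-0.14, -0.19, -0.12 and 0), nor Kcnh5 in mDPC (-0.14), while the nearest tested genes on either side averaged 0.09 (Sgpp1, with -0.76 in mESC) and 0 (Gm7862, with 0.7 in NPC). An exchange of the labels of the whole lines stays open too. LY3201 called 1593 genes on average in arrays labelled WT and 1 in arrays labelled BERKO. With one distribution it called 268 higher and 103 lower in WT, and 0 and 1 in BERKO. These counts run the way the labels say, but how much of them needs ERβ was not settled. The 685 genes that differed directly with one distribution have no bearing on this, since exchanged labels would leave that number unchanged.

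Genotype averaged over stages called 6585 genes, and the highest count among the other splits of 100 drawn within stage was 2433, with 1 split, the real one, reaching it. This argues against a chance division of these arrays only. All arrays of a label come from 1 line, so any difference between the lines would set the real split apart, whether or not it comes from loss of ERβ. For LY3201 in WT, 1 split, the real one, reached 1593.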
